A study of Homo sapiens with 5 samples.

How the data were processed

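RNA of single blood progenitor cells was measured in 3 MF samples and 2 HD samples, grouped by the labels. Per the labels' protocols, frozen mononuclear cells were thawed, CD34-positive cells without lineage markers were sorted by flow cytometry, and libraries were made with the first version of the 10x 3′ chemistry. The values used are whole-number counts of UMIs per gene and cell, as deposited by the authors in 1 table of 33694 genes and 47804 cells. Per the submitters' processing notes, Cell Ranger 2.0.0, the GRCh38 build and limma were used; the settings and any equalising of depth between libraries are not given in the sources used here. Cells were assigned to libraries by the number at the end of their barcode, and libraries to groups by barcodes shared with 2 further deposited tables, 1 per group. Those tables shared 9425, 8818, 8488, 10463 and 10584 cells with the libraries of the main table, in which the UMIs of these cells came to 0.99 (both HD libraries) and 1.00 (MF libraries) of those in the group tables. Of the counts above 0 in either table, 25.0% differed in HD replicate 1 and 3.16% in HD replicate 2. In MF replicates 1, 2 and 3 the shares were 5.69%, 0% and 1.37%. The reason for these differences was not tested. All tests were run within the main table. The 101 genes of X inactivation and the Y chromosome were left out, which left 33593.

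Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were to be kept, and every deposited cell passed (lowest 503 genes, highest 9.99%). The libraries held 9445 and 8820 HD cells and 8492, 10463 and 10584 MF cells. Scrublet called 4 doublets (0.0084% of cells), too few to have worked, so doublets were kept and the 5% of cells with the highest scores were left out in an alternative. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 components were taken, and cells were grouped with 15 neighbours and the Leiden method at resolution 1. Genes of the pathway lists that are no cell type marker were left out of this step. A cluster was named "-like" from fixed marker lists when at least 3 markers of the class were at least 1.5 times as high there as elsewhere. It stayed unnamed otherwise, or when its 10 leading genes held more markers of another class than of this one. Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2 and scipy 1.17.1 were used.

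Raw counts were summed per library, or per library and class, and tested with edgeR 4.0.16 (R 4.3.3): TMM normalization, a filter on low counts, the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. Classes were tested with at least 20 cells in at least 2 libraries of each group, which held for HSC/MPP-like, erythroid-like and eosinophil/basophil/mast-like cells. Megakaryocyte-like cells were compared with all other cells of named classes within the MF samples, with the sample as block, over list genes left out of the clustering. Unnamed cells were left out. Since no HD library had 20 megakaryocyte-like cells by cluster, MF and HD megakaryocyte-like cells were compared in a class made by giving each cell to the marker list with the highest mean score. Shares were compared with exact permutation tests (two-sided, the smaller tail p doubled), with exact Clopper-Pearson intervals at 95%. Cells were thinned to 2000 UMIs before shares of cells with a UMI were taken. Intervals and floors of 3 counts cover counting error only.

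In all 24 gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) and again with an estimated correlation: 12 of cell type markers, 10 of pathways and 2 by symbol (mitochondrially encoded and ribosomal protein genes). Genes were named by rule. Among genes past the threshold with a mean of at least 20 CPM and groups that did not overlap, these were the 12 with the largest rise and the 12 with the largest fall. Up to 4 members of each list with the smallest p, and C6orf25 (MPIG6B), PF4, VWF, ITGA2B, TGFB1, CD9 and CXCR4 in every comparison, were added. Some genes named by these rules are not reported here. The groups, tests, lists, markers, naming rule and most alternative settings were fixed before the data were examined. Alternatives included DESeq2 1.42.0, its size factors, no filter on low counts, other clusterings, stricter cell filters, thinned cells and leaving out each sample.

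The tests were tried on counts simulated from the library means, with 200 genes changed. In whole libraries 3% of genes changed by 2-fold and 47% of those changed by 4-fold were recovered, with 5 false calls among 55. In HSC/MPP-like cells the shares were 11% and 69%, with 16 false calls among 96, and for megakaryocyte-like against other cells 78% and 92%, with 14 among 184. Gene positions were taken from an annotation of GRCh38.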

Results

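Blood progenitors sorted as CD34-positive and lineage-negative from frozen mononuclear cells were profiled by droplet-based 3′ single-cell RNA sequencing in 3 myelofibrosis (MF) samples and 2 healthy donor (HD) samples. Myelofibrosis is a blood cancer in which scar tissue replaces the marrow, and the title of the series names haematopoiesis biased to megakaryocytes, the precursors of platelets, as its subject. The HD samples were described as mobilized, meaning that progenitors had been driven from marrow into blood, and nothing of the kind was stated for MF, so mobilization could not be separated from group. Unique molecular identifiers (UMIs) were counted per gene in 18265 HD and 29539 MF cells. The HD libraries held 60976615 and 58482024 UMIs, with medians of 6243 and 6250.5 UMIs per cell. The MF libraries held 56289450, 86353636 and 89838866 UMIs, with medians of 5836.5, 7289 and 7444.5. All pairs of libraries differed by more than sampling noise (chi-square per degree of freedom between 108 and 442), so each was counted as 1 sample. Replicate numbers only name libraries and were not tied to individual sample titles. The p-values below measure the spread between these samples, and counting intervals cover counting error only.

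The first comparison asked how the cell classes of the progenitor pool differed between MF and HD. Megakaryocyte-like cells, named from transcripts such as PF4 and PPBP (chemokines stored in platelet granules), made up 10.7% ± 8.30 (SD, n = 3) of MF cells and 0.096% ± 0.104 (SD, n = 2) of HD cells. Cells like haematopoietic stem cells and multipotent progenitors (HSC/MPP-like) made up 39.6% ± 12.7 (SD, n = 3) in MF and 80.6% ± 5.74 (SD, n = 2) in HD. Erythroid-like cells, named from transcripts such as TFR2 (a transferrin receptor) and CA1 (carbonic anhydrase), with haemoglobin genes and KLF1 raised in clusters 9 and 11 alone, made up 23.1% ± 8.61 (SD, n = 3) in MF and 14.4% ± 7.90 (SD, n = 2) in HD. Neutrophil-like cells, named from granule enzymes such as MPO, made up 9.71% ± 12.9 (SD, n = 3) against 0.399% ± 0.259 (SD, n = 2), and 24.7% of MF replicate 3. Eosinophil/basophil/mast-like cells made up 5.02% ± 6.70 (SD, n = 3) against 0.902% ± 0.632 (SD, n = 2), and 12.7% of MF replicate 3. Without that replicate the neutrophil-like difference went from 9.32 to 1.85 percentage points and the eosinophil/basophil/mast-like one from 4.11 to 0.255. The weight of that replicate depended on the clustering. With genes centred within each library, neutrophil-like cells numbered 904, 1684 and 2269 in MF and 63 and 73 in HD. By marker score they numbered 694, 956 and 1221 in MF and 206 and 245 in HD. Without marker genes in the clustering, MF replicate 3 again held most, at 1197 against 41 and 166 in MF replicates 1 and 2.

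The megakaryocyte-like share was 1.21%, 14.5% and 16.5% in the MF libraries (103, 1520 and 1742 cells; 95% Clopper-Pearson interval of the lowest 0.991% to 1.47%). It was 0.169% and 0.0227% in the HD libraries (16 and 2 cells; intervals 0.0969% to 0.275% and 0.0027% to 0.0819%). The MF libraries thus lay above the HD libraries by more than counting error. When the marker genes were left out of the clustering, an alternative added after the data had been seen, the lowest MF share was 1.11% and the highest HD share 0.0953%. Lymphoid progenitor-like cells made up 7.34% ± 12.5 (SD, n = 3) in MF and 3.18% ± 2.37 (SD, n = 2) in HD. That mean rested on MF replicate 1 at 21.8%, and without it the difference was −3.06 percentage points. Cells left unnamed, mostly in clusters led by cell division genes, made up 4.55% ± 2.28 (SD, n = 3) and 0.464% ± 0.0627 (SD, n = 2). With 3 samples against 2, the exact permutation test as run (two-sided, the smaller tail p doubled) can give no p below 0.2. The HSC/MPP-like, megakaryocyte-like, neutrophil-like and unnamed shares reached it (0.35 after Benjamini-Hochberg adjustment over 7 classes). The exact permutation p was 0.4 for the eosinophil/basophil/mast-like share (adjusted 0.56), 0.6 for the erythroid-like share (adjusted 0.7) and 1.0 for the lymphoid progenitor-like share. The erythroid-like difference of 8.72 percentage points ran from 3.13 to 14.3 as each sample was left out and turned to −1.01 when genes were centred within each library, and the CD34 sort limits all shares to cells inside that gate.

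**Figure D1:**
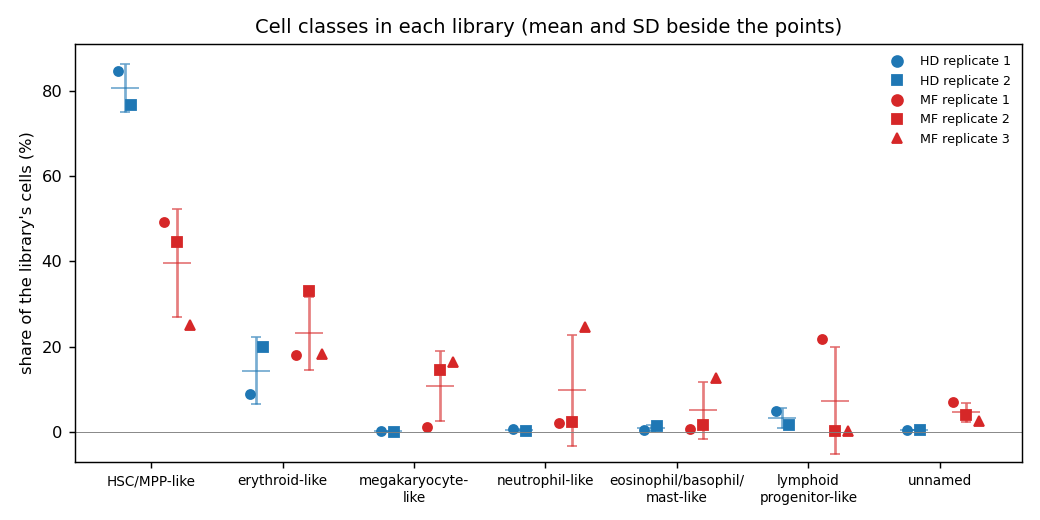
Share of each library's cells (%, vertical axis) in the 7 cell classes (horizontal axis) for 2 HD and 3 MF libraries, with the mean and SD of each group as bars. The MF libraries hold 1.21% to 16.5% megakaryocyte-like cells, all above the HD libraries at 0.169% and 0.0227%.

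Counts summed over all cells of each library were compared next, to ask which genes differed between MF and HD progenitors as a whole. PF4 stood at 256 ± 145 CPM (counts scaled to the same library total; SD, n = 3) in MF and 0.871 ± 0.0356 (SD, n = 2) in HD, and PPBP at 89.4 ± 40.5 against 0.129 ± 0.183 CPM. The haemoglobin genes HBD (537 ± 171 against 41.3 ± 14.4 CPM) and HBB (275 ± 201 against 14.4 ± 4.48 CPM) and the cell division gene MKI67 (43.0 ± 13.6 against 3.96 ± 1.32 CPM) were also higher in MF. HSPA1A, the gene of a stress-induced chaperone, was lower, at 20.6 ± 4.17 CPM in MF and 1464 ± 102 in HD. Of 16212 genes tested, 74 were higher and 87 lower in MF by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Groups did not overlap for 28.1% of genes, against 20% by chance, and the median log2 change of all genes was 0.01.

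PPBP rose by 9.39 ± 1.01 on the log2 scale (SE) and PF4 by 8.20 ± 0.75 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00972 and 0.00521). PPBP had 0 UMIs in 1 HD library, so its fold is uncertain: the log2 change ran from 8.42 to 15.69 as each sample was left out. The genes lie side by side on chromosome 4 of GRCh38, PF4 at 73981077 to 73982124 and PPBP at 73987038 to 73988197. CMTM5, a membrane protein gene of megakaryocytes, rose by 6.68 ± 0.89, and LAT, a signalling adaptor of T cells and platelets (chromosome 16, 28984826 to 28990783), by 5.30 ± 0.88 (edgeR, Benjamini-Hochberg adjusted p = 0.0160 and 0.0323). C6orf25, now called MPIG6B, encodes an inhibitory receptor of megakaryocytes (chromosome 6, 31718594 to 31726714) and rose by 2.85 ± 0.40, from 9.07 ± 0.539 to 65.3 ± 26.4 CPM. VWF, the adhesive glycoprotein of platelets and endothelium (chromosome 12, 5948874 to 6124770), rose by 2.43 ± 0.41, and LTBP1, which binds latent TGF-beta (chromosome 2, 32946972 to 33399509), by 5.58 ± 0.90 (edgeR, Benjamini-Hochberg adjusted p = 0.0331 and 0.0296). Of the other genes followed in each comparison, ITGA2B (platelet integrin alpha IIb) had a log2 change of 3.14 ± 0.63, CD9 of 1.55 ± 0.45, TGFB1 of 0.68 ± 0.34 and CXCR4 (a marrow homing receptor) of −1.30 ± 0.39. None of these 4 passed the threshold (edgeR, Benjamini-Hochberg adjusted p = 0.0587, 0.167, 0.497 and 0.171).

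Among fixed marker lists, 8 of 20 megakaryocyte genes rose and none fell (18 adjusted over the list alone). Of 18 erythroid genes 4 rose (13 adjusted over the list alone, with 1 lower), among them HBD by 3.70 ± 0.40, HBB by 4.25 ± 0.68 and AHSP, which stabilises alpha globin, by 2.26 ± 0.38. The HBD rise does not stand for erythroid-like cells alone. In megakaryocyte-like cells of the MF libraries HBD was at 2640, 2461 and 1319 CPM. Counts of HBA1 and HBG2 are uncertain because near-identical copies share reads. Of 14 cycling genes 7 rose (14 adjusted over the list alone), including MKI67 by 3.44 ± 0.41 and the topoisomerase gene TOP2A by 2.66 ± 0.32. Of 10 neutrophil genes 1 rose (9 adjusted over the list alone): MPO, at 2.19 ± 0.36. These lists, and those of monocytes (0 of 9 rose; 6 adjusted over the list alone) and eosinophil/basophil/mast cells (0 of 12, and 0 alone), lay above other genes by camera (adjusted p = 1.63e-38, 7.14e-16, 8.64e-31, 1.79e-11, 4.23e-05 and 0.0141). With an estimated correlation the adjusted p of these 6 lists was 0.149, 0.149, 0.149, 0.184, 0.149 and 0.411. Of 12 HSC/MPP genes 2 fell (5 adjusted over the list alone), CRHBP (log2 change −2.21) and PROM1 (−1.72) (camera adjusted p = 4.88e-07; adjusted p = 0.219 with an estimated correlation). Of 10 lymphoid progenitor genes 1 fell (3 adjusted over the list alone), DNTT, the polymerase of antigen receptor rearrangement (camera adjusted p = 0.00474; adjusted p = 0.411 with an estimated correlation). Lists of dendritic, T or NK, mature B or plasma, and stromal or endothelial cells had no called member and did not pass (camera adjusted p = 0.136, 0.0677, 0.292 and 0.366). Adjusted over the list alone they had 2 lower, 2 higher, 0, and 1 higher with 2 lower members.

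Among the pathway lists, 5 of 29 immediate early and heat shock genes fell (11 adjusted over the list alone) and none rose: the heat shock genes HSPA1A, HSPA1B, DNAJB1 and HSP90AA1 and the immediate early gene NR4A1. JAK-STAT targets had 2 of 22 lower (3 adjusted over the list alone, with 1 higher), the cytokine gene OSM (log2 change −1.72) and the repressor gene BCL6 (−3.36). Homing and adhesion genes had 2 of 21 lower (5 adjusted over the list alone, with 1 higher). These 3 lists and the NF-kB and inflammatory cytokine list (0 of 25; 1 lower alone) lay below other genes by camera (adjusted p = 1.23e-24, 0.0308, 0.0251 and 0.00412). With an estimated correlation the adjusted p was 0.184, 0.219, 0.219 and 0.429. The megakaryocyte transcription and signalling list had 0 of 29 called (4 higher adjusted over the list alone; camera adjusted p = 1.09e-04 upward; adjusted p = 0.391 with an estimated correlation). Mitochondrially encoded genes (0 of 13 called) lay above, and ribosomal protein genes (1 of 80 called, RPS26, lower) below other genes (camera adjusted p = 0.0251 and 0.00236; adjusted p = 0.532 and 0.607 with an estimated correlation). The lists of fibrosis and growth factors (2 higher and 1 lower of 29; 5 and 4 alone), interferon response (0 of 30; 0 alone) and unfolded protein response (0 of 22; 0 alone) did not pass (camera adjusted p = 0.0677, 0.0584 and 0.366). Nor did hypoxia and glycolysis (1 lower of 24, ADM; 1 alone) or haematopoietic transcription factors (1 higher, NFIB, and 1 lower, CEBPB, of 35; 2 and 3 alone), at camera adjusted p = 0.178 and 0.0536. The median and mean log2 change differed in sign for the stromal (0.47 and −0.40) and hypoxia (0.03 and −0.39) lists.

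These counts leaned on single libraries: they were 6 higher and 21 lower without HD replicate 1, 7 and 36 without HD replicate 2, 393 and 255 without MF replicate 1, and 71 and 133 without MF replicate 2. PF4, PPBP, HSPA1A, HSPA1B, HSPA6, DNAJB1, HIST1H2AC, HIST1H2BG, RGS1 and ADM kept their calls without any 1 of the 5 samples, while the other 32 of 42 named calls, C6orf25 and VWF among them, did not.

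**Figure D2:**
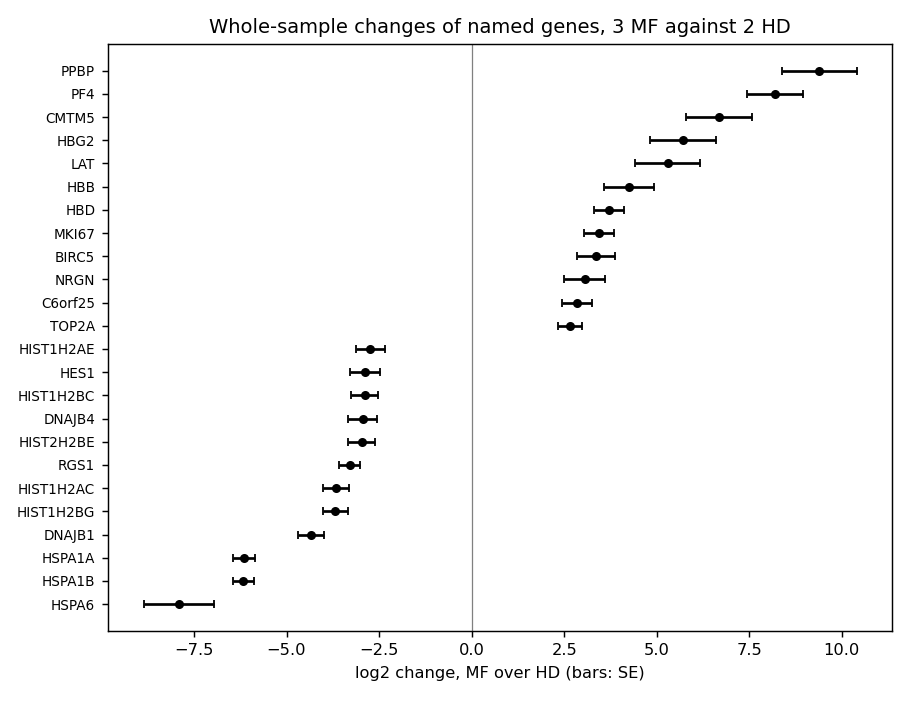
Log2 change of MF over HD (horizontal axis; bars, SE) of the 12 genes with the largest rise and the 12 with the largest fall among those that passed the test in whole-library sums, 3 MF against 2 HD libraries. PPBP (9.39) and PF4 (8.20) rose most and HSPA6 (−7.91) fell most.

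Within HSC/MPP-like cells, the comparison asked whether MF and HD differed in the same cell class. VWF and C6orf25 were higher there too: VWF stood at 16.2 ± 3.11 CPM (SD, n = 3) in MF and 2.12 ± 0.408 (SD, n = 2) in HD, and C6orf25 at 41.8 ± 7.05 and 6.51 ± 0.685. RXFP1, the relaxin receptor gene, stood at 39.5 ± 16.1 against 2.87 ± 2.34 CPM, and the imprinted long non-coding RNA MEG3 at 131 ± 27.7 against 22.0 ± 12.9. QPRT, an enzyme of NAD synthesis, and CD84, a leukocyte adhesion receptor, were also higher, at 78.8 ± 14.3 against 20.3 ± 3.61 and 36.2 ± 0.748 against 12.8 ± 3.15 CPM. HSPA1A was lower, at 28.5 ± 0.954 CPM in MF and 1427 ± 129 in HD. Of 14939 genes tested, 43 were higher and 65 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjustment); groups did not overlap for 21.7% of genes, against 20% by chance.

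VWF rose by 2.93 ± 0.35 and C6orf25 by 2.68 ± 0.29 on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 0.00719 and 0.00527). RXFP1 rose by 3.77 ± 0.61, MEG3 by 2.57 ± 0.41, QPRT by 1.95 ± 0.28 and CD84 by 1.5 ± 0.27 (edgeR, Benjamini-Hochberg adjusted p = 0.0303, 0.0300, 0.0170 and 0.0441). RXFP1 and MEG3 also stood among the leading genes of clusters made of MF cells. PF4 (19.4 ± 8.92 against 0.0862 ± 0.0224 CPM) and PPBP (11 ± 3.87 against 0.0306 ± 0.0433 CPM) passed the test as well, on 8 and 3 HD UMIs. CXCR4, CD9, ITGA2B and TGFB1 had log2 changes of −0.86 ± 0.39, 1.12 ± 0.29, 2.12 ± 0.55 and −0.15 ± 0.24 and did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.635, 0.178, 0.174 and 0.999). Of 20 megakaryocyte list genes 6 rose (16 adjusted over the list alone) and of 17 erythroid genes 2 rose, HBD and HBB (6 adjusted over the list alone, with 1 lower). Of the 6 called megakaryocyte list genes only 1, VWF, stood at over 2 times its level in neutrophil-like cells in every MF library. LAT stood at 0.887 to 1.44 times that level, CMTM5 at 1.68 to 1.87, HBD at 1.18 to 1.40, HBB at 0.893 to 1.37 and CD84 at 0.627 to 0.796. The megakaryocyte, erythroid and cycling lists, the last with 0 of 14 called (2 higher adjusted over the list alone), lay above other genes by camera (adjusted p = 2.19e-39, 9.62e-07 and 5.54e-05; adjusted p = 0.0950, 0.128 and 0.166 with an estimated correlation). So did lists with no called member: interferon response genes (0 of 29), neutrophil markers (0 of 10; 1 higher adjusted over the list alone) and mitochondrially encoded genes (0 of 13). Camera gave adjusted p = 0.00410, 0.0327 and 0.0289 (adjusted p = 0.447, 0.447 and 0.522 with an estimated correlation).

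Below other genes lay immediate early and heat shock genes (8 of 28 fell, 12 adjusted over the list alone), unfolded protein response genes (1 of 22 fell, HERPUD1; 4 alone) and hypoxia and glycolysis genes (2 of 24 fell, the glucose transporter gene SLC2A3 and ADM). Camera gave them adjusted p = 2.47e-28, 5.54e-05 and 1.37e-04 (adjusted p = 0.166, 0.358 and 0.358 with an estimated correlation). JAK-STAT targets had 2 of 22 lower, OSM (log2 change −1.78) and BCL6 (−2.69) (camera adjusted p = 0.0327; adjusted p = 0.350 with an estimated correlation). Lymphoid progenitor markers had 1 of 9 lower, VPREB1 (2 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0327; adjusted p = 0.367 with an estimated correlation). The HSC/MPP-like cells came from clusters 0, 1, 5 and 15 in HD and clusters 2, 3 and 6 in MF. At a coarser clustering (resolution 0.5) the class kept only 20 and 47 cells in 2 MF libraries, where 3 higher genes and 0 lower ones were called. The counts were 21 higher genes without HD replicate 1, 10 higher and 20 lower without HD replicate 2, 80 higher without MF replicate 1 and 75 higher with 119 lower without MF replicate 2. Of 31 named calls 19 were lost when some 1 sample was left out, VWF, C6orf25, RXFP1, MEG3, QPRT, CD84, HBB, HBD, OSM, BCL6, HERPUD1, SLC2A3, ADM and VPREB1 among them without HD replicate 2.

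Shares of cells with a UMI were compared after thinning every cell to 2000 UMIs. In HSC/MPP-like cells, VWF was found in 3.29% ± 0.826 (SD, n = 3) of MF and 0.408% ± 0.0982 (SD, n = 2) of HD cells, and in 0.459% of MF neutrophil-like cells, which should lack it. C6orf25 was found in 7.97% ± 1.28 (SD, n = 3) and 1.30% ± 0.168 (SD, n = 2), and in 3.98% of MF neutrophil-like cells. Its share was higher in MF in erythroid-like cells too, at 10.7% ± 1.85 (SD, n = 3) against 4.48% ± 0.141 (SD, n = 2). PF4 was found in 3.97% of MF HSC/MPP-like cells, close to the 3.64% of MF neutrophil-like cells, and PPBP in 1.93% against 2.19%, so these shares were close to those of that class. RNA outside cells was not measured, so whether this level is background was not tested. The median depth was 4977 to 6079 UMIs in MF HSC/MPP-like cells and 6501 to 8229 in MF neutrophil-like cells. Without thinning the shares were 8.64% against 1.25% for VWF and 21.3% against 3.87% for C6orf25. Exact permutation p (two-sided, the smaller tail p doubled) was 0.2 for VWF, C6orf25, PF4 and PPBP, the smallest that this test allows with 3 against 2 samples (adjusted 0.225 over 18 shares). In 64 HD cells and 0 MF cells the depth was below 2000 UMIs.

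**Figure D3:**
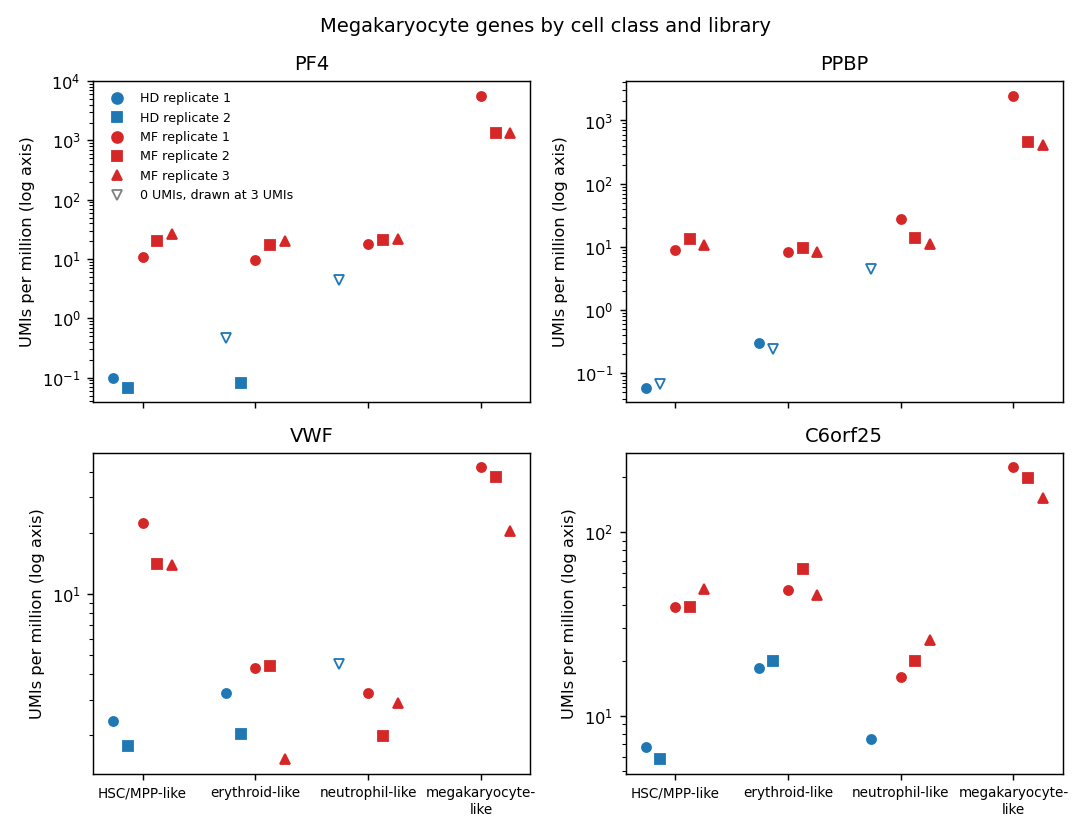
UMIs in CPM (log axis) of PF4, PPBP, VWF and C6orf25 in 4 cell classes (horizontal axis) for each library with at least 20 cells of the class; open triangles mark 0 UMIs, drawn at 3 UMIs. In MF, PF4 lies at a like level in the HSC/MPP-like, erythroid-like and neutrophil-like classes, while VWF is higher in HSC/MPP-like than in neutrophil-like cells.

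HSPA1A, HSPA1B and DNAJB1 fell in each of the 3 classes tested. Of the immediate early and heat shock list, 8 of 28 fell in HSC/MPP-like, 4 of 28 in erythroid-like and 4 of 25 in eosinophil/basophil/mast-like cells (12, 12 and 10 adjusted over the list alone, with 3 higher in the last). In the latter 2 classes camera gave adjusted p = 5.23e-42 and 2.65e-16 (adjusted p = 0.110 and 0.356 with an estimated correlation). In whole libraries HSPA6, an inducible HSP70 gene (chromosome 1, 161524540 to 161526910), had a log2 change of −7.91 ± 0.95 and the co-chaperone gene DNAJB1 of −4.34 ± 0.36 (edgeR, Benjamini-Hochberg adjusted p = 0.0116 and 0.00362). HSPA1B (chromosome 6, 31827735 to 31830255) had a log2 change of −6.17 ± 0.28 and HSPA1A (chromosome 6, 31815464 to 31817946) of −6.15 ± 0.30 (edgeR, Benjamini-Hochberg adjusted p = 8.95e-05 for both). HSPA1A and HSPA1B are near-identical, so the split of reads between them is uncertain. Within HSC/MPP-like cells the log2 change was −5.65 ± 0.26 for HSPA1A, −2.35 ± 0.23 for HSPB1, a small heat shock protein gene, and −4.31 ± 0.58 for the co-chaperone gene BAG3 (edgeR, Benjamini-Hochberg adjusted p = 4.89e-05, 0.00346 and 0.0127). HD cells included 2 clusters led by heat shock genes, which held 17.8% and 41.6% of the HD libraries and at most 0.271% of an MF library. Without these clusters, a setting added after the data had been seen, HSPA1A (log2 change −5.27) and DNAJB1 (−3.30) were still called in whole libraries, and 128 genes were higher. NR4A1 (log2 change −3.58 ± 0.62 before and −3.27 ± 0.69 after), HSP90AA1 (−1.64 ± 0.26 and −1.09 ± 0.25) and DNAJB4 (−2.95 and −1.63) were no longer called but stayed below 0 (edgeR, Benjamini-Hochberg adjusted p = 0.0598, 0.0718 and 0.0905).

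**Figure D4:**
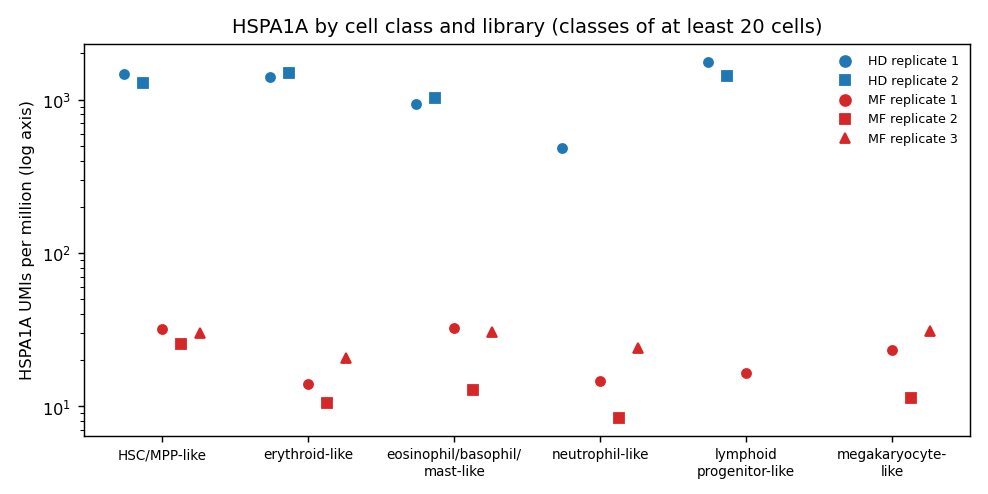
HSPA1A UMIs in CPM (log axis) by cell class (horizontal axis) and library, for classes of at least 20 cells. HD libraries lie at or above 484 and MF libraries at or below 32.3 on this scale in every class shown.

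In erythroid-like cells 9 genes were higher and 20 lower of 13214 tested, and in eosinophil/basophil/mast-like cells 0 were higher and 10 lower of 6678 (edgeR quasi-likelihood, Benjamini-Hochberg adjustment). At an unadjusted p under 0.05 there were 795 and 245 genes, and DESeq2 called 5 higher and 15 lower genes in the latter class. Groups did not overlap for 19.8% and 17.0% of genes, against 20% by chance. In erythroid-like cells the log2 change was −6.70 ± 0.33 for HSPA1A and −4.41 ± 0.40 for DNAJB1 (edgeR, Benjamini-Hochberg adjusted p = 4.63e-05 and 0.00404). BIRC5, a mitosis and survival gene, rose by 2.89 ± 0.40, from 2.23 ± 0.202 to 16.7 ± 4.89 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.0373). MPO, a marker gene of the neutrophil list, was called higher too, with a log2 change of 2.44 to 2.95 as each sample was left out. PF4 was at 15.6 ± 6.26 CPM in MF and 0.0423 ± 0.0598 in HD erythroid-like cells, on 1 HD UMI. Its UMIs came to 16.3 CPM in MF erythroid-like and 21.2 in MF neutrophil-like cells, so PF4 was no higher in the erythroid-like class. VWF had a log2 change of 0.34 (edgeR, Benjamini-Hochberg adjusted p = 0.999). In eosinophil/basophil/mast-like cells the log2 change was −5.4 ± 0.34 for HSPA1A, −2.15 ± 0.29 for HSPB1 and −2.11 ± 0.34 for ERN1, a sensor of unfolded proteins (edgeR, Benjamini-Hochberg adjusted p = 1.56e-06, 0.00401 and 0.0199), but HSPB1 and ERN1 were not called when some 1 sample was left out. The erythroid-like cells came from cluster 7 in HD, led by heat shock genes, and from clusters 4, 9 and 11 in MF. The eosinophil/basophil/mast-like cells came from cluster 14 (1010 MF cells and 11 HD cells, 96.5% of all from MF replicate 3) and cluster 18 (565 and 151). Without cluster 7 the counts were 0 higher and 4 lower, and BIRC5 and PF4 were not called. The erythroid-like counts were also 1 and 9 without HD replicate 1, 0 and 6 without HD replicate 2, 81 and 177 without MF replicate 2 and 18 higher without MF replicate 3. In the other class they were 16 lower without HD replicate 1, 6 lower without HD replicate 2 and 2 higher without MF replicate 1.

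A further comparison, within the 3 MF samples, asked how megakaryocyte-like cells differed from all other cells of named classes. It covered pathway genes that had played no part in the clustering. LTBP1 and TGFB1 were higher: LTBP1 stood at 178 ± 42.0 CPM (SD, n = 3) in megakaryocyte-like and 4.47 ± 2.14 in other cells, and TGFB1, the cytokine gene tied to marrow fibrosis (chromosome 19, 41301587 to 41353911), at 218 ± 35.7 and 48.7 ± 6.77. CD34 and MYB were lower: CD34 stood at 48.5 ± 14.3 against 152 ± 54.9 CPM, and the transcription factor gene MYB at 46.5 ± 9.60 against 130 ± 15.4. BST2, an antiviral membrane protein gene induced by interferon, was lower, at 37.3 ± 11.3 against 223 ± 9.23 CPM. Of 238 list genes 91 were higher and 97 lower, by the edgeR quasi-likelihood test with the sample as block and Benjamini-Hochberg adjustment over 14528 genes. The share of all 14528 genes that passed is not given here, so the counts for single lists below have no baseline beside them. Only camera set the lists against other genes.

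LTBP1 rose by 5.32 ± 0.28 on the log2 scale, THBS1 (thrombospondin) by 5.17 ± 0.31 and TGFB1 by 2.17 ± 0.11, each higher in 3 of 3 samples (edgeR, Benjamini-Hochberg adjusted p = 2.21e-10, 1.02e-09 and 1.38e-10). Of 23 fibrosis and growth factor genes 15 rose and 5 fell, and the same counts passed adjusted over the list alone (camera adjusted p = 2.73e-04; adjusted p = 0.301 with an estimated correlation). Of 28 megakaryocyte transcription and signalling genes 21 rose and none fell (22 adjusted over the list alone; camera adjusted p = 2.14e-13; adjusted p = 0.301 with an estimated correlation). They included TUBA4A (alpha tubulin) by 3.46 ± 0.13, ARHGAP6 by 4.42 ± 0.20 and FERMT3, which activates integrins, by 2.32 ± 0.12. Of 22 unfolded protein response genes 13 rose and none fell, among them MANF by 2.18 ± 0.13 and the endoplasmic reticulum chaperone gene HSPA5 by 1.47 ± 0.09 (camera adjusted p = 2.80e-06; adjusted p = 0.386 with an estimated correlation). Of 23 hypoxia and glycolysis genes 17 rose and 2 fell, with SLC2A3 up by 3.49 ± 0.17 and the pyruvate kinase gene PKM by 1.75 ± 0.10 (camera adjusted p = 8.86e-06; adjusted p = 0.441 with an estimated correlation).

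Of 29 interferon response genes 22 fell and 3 rose (23 and 3 adjusted over the list alone), with a log2 difference of −2.71 ± 0.15 for BST2 and −2.05 ± 0.13 for XAF1 (camera adjusted p = 5.79e-06; adjusted p = 0.386 with an estimated correlation). Of 32 haematopoietic transcription factor genes 20 fell and 6 rose (20 and 7 adjusted over the list alone), with ERG at −1.94 ± 0.15, BCL11A at −1.79 ± 0.13 and HOXA9 at −1.60 ± 0.15 (camera adjusted p = 0.00268; adjusted p = 0.572 with an estimated correlation). Of 21 homing and adhesion genes 13 fell and 4 rose (camera adjusted p = 0.0265; adjusted p = 0.586 with an estimated correlation). CD44 and ICAM3, which mediate leukocyte adhesion, had log2 differences of −2.27 ± 0.12 and −2.37 ± 0.13. ESAM, a junction protein gene of platelets and endothelium, had one of 3.65 ± 0.13, and the cyclin gene CCND3, a JAK-STAT target, one of 2.45 ± 0.12. Of 24 NF-kB and inflammatory cytokine genes 17 fell and 4 rose (camera adjusted p = 0.0299; adjusted p = 0.586 with an estimated correlation), the chemokine gene CXCL3 rising by 2.56 ± 0.33. JAK-STAT targets (5 rose and 12 fell of 22) and immediate early and heat shock genes (10 rose and 9 fell of 28; 10 and 11 alone) did not pass as lists (camera adjusted p = 0.562 and 0.99; adjusted p = 0.600 and 0.99 with an estimated correlation). CXCR4 passed the test with a log2 difference of −0.91 ± 0.28 but was higher in megakaryocyte-like cells in 1 of 3 samples, and it was not called without MF replicate 2 or without MF replicate 3.

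**Figure D5:**
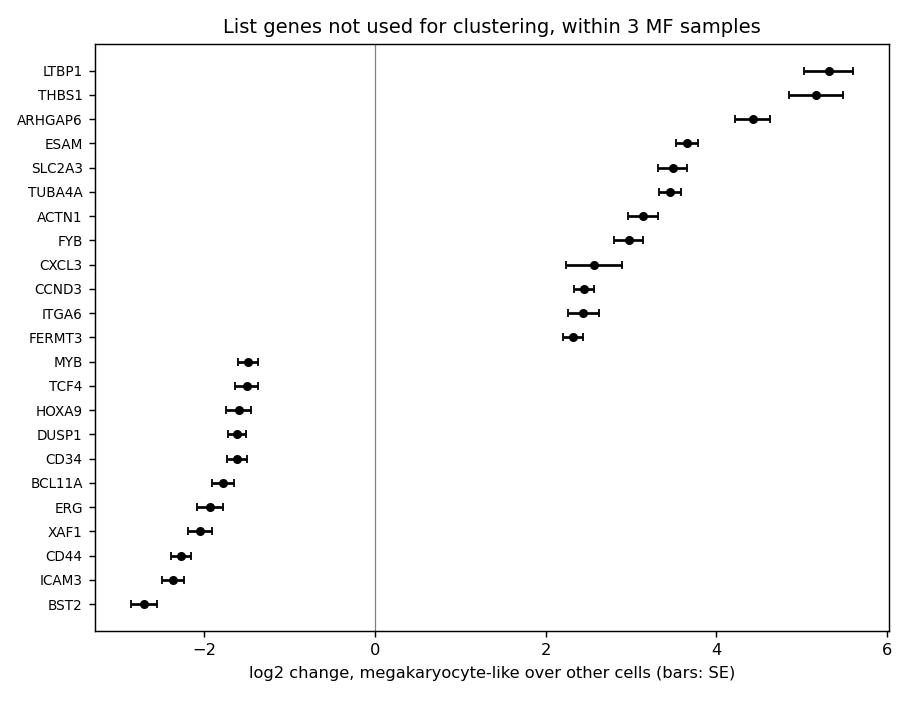
Log2 change of megakaryocyte-like over other cells (horizontal axis; bars, SE) within 3 MF samples, for list genes with a mean of at least 20 CPM and a large rise or a large fall among those left out of the clustering. Of the genes shown, LTBP1 (5.32) and THBS1 (5.17) lie highest and BST2 (−2.71) lowest.

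No HD library had 20 megakaryocyte-like cells by cluster, so megakaryocyte-like cells of MF and HD were compared with cells assigned by marker score. PF4 stood at 1509 ± 206 CPM (SD, n = 3) in MF and 85.0 ± 20.5 (SD, n = 2) in HD, and LTBP1 at 131 ± 44.8 and 18.0 ± 4.54. PF4 rose by 4.16 ± 0.34 on the log2 scale and LTBP1 by 2.89 ± 0.47 (edgeR, Benjamini-Hochberg adjusted p = 0.000183 and 0.0194). PF4 is part of the score, so its change is no independent evidence. LTBP1 is not part of it, but within MF it was much higher in megakaryocyte-like than in other cells. Its change may therefore follow from the different cell mixtures of the class, given below. CD36, a fatty acid and thrombospondin receptor gene, had 14210 UMIs in MF and 4 in HD, and the cyclin gene CCNB1 2518 and 2, too few in HD for a firm fold. Of 10542 genes tested 31 were higher and 41 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjustment). The cell division genes MKI67, CENPF and RRM2 were among the higher ones, on 19, 26 and 8 HD UMIs. The haemoglobin gene HBD was too, on 233 HD UMIs. VWF, C6orf25, CD9 and TGFB1 had log2 changes of 0.21, 1.36, 2.06 and 1.22 and were not called.

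A class taken from a score is a range of cells and not a type, and it sat in different clusters in each group: 7.29% and 0.877% of its HD cells and 21.0%, 79.8% and 84.0% of its MF cells lay in megakaryocyte-like clusters. It held 96 and 114 HD cells and 419, 1675 and 1512 MF cells, of which 50, 55, 156, 202 and 160 lay near the boundary. The median number of megakaryocyte marker UMIs per cell was 3 and 4 in HD and 6, 41 and 50 in MF, and that of HSC/MPP marker UMIs 5 and 3 against 6, 3 and 3. Erythroid marker UMIs differed as well, with medians of 1 and 2 in HD and 2, 13 and 11 in MF. The counts were 2 higher and 8 lower without HD replicate 1, 2 and 11 without HD replicate 2, 523 and 334 without MF replicate 1, and 9 and 24 without MF replicate 2. LTBP1 was not called without HD replicate 1, HD replicate 2 or MF replicate 2.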

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

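The comparison of HSC/MPP-like with erythroid-like cells, the tests of free RNA, of handling or mobilization and of clusters that follow libraries, the count over splits, and the setting without clusters led by heat shock genes were chosen after the results had been seen.

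The contrast of megakaryocyte-like cells, assigned by marker score, with other cells differed between MF and HD for 33 genes that were higher in MF and 13 that were lower, of 16047 tested (edgeR quasi-likelihood interaction of class and group, Benjamini-Hochberg adjustment). This contrast compares different cell mixtures, since 7.29% and 0.877% of the HD cells and 21.0%, 79.8% and 84.0% of the MF cells of the class lay in megakaryocyte-like clusters. LMNA, a nuclear lamina gene, differed by 2.87 ± 0.40 on the log2 scale, STOM, a membrane protein gene, by 2.14 ± 0.26 and TMSB4X, which binds actin, by 1.97 ± 0.26 (edgeR, Benjamini-Hochberg adjusted p = 0.00218, 0.000830 and 0.00126). CNRIP1 differed by −2.32 ± 0.33 and the growth factor gene EREG by −1.68 ± 0.25 (edgeR, Benjamini-Hochberg adjusted p = 0.00240 and 0.00295). Of the genes in the score, CD9 differed by 1.41 ± 0.27 and PF4 by −3.61 ± 0.55 (edgeR, Benjamini-Hochberg adjusted p = 0.0310 and 0.00391). After 1 CPM was added to each value, the mean log2 contrast of PF4 was 6.19 in MF and 6.18 in HD and the groups overlapped. That addition shrinks the HD contrast, since PF4 stood at 0.0846 CPM in HD HSC/MPP-like cells, so these means cannot decide on the call. Both genes are part of the score, so such calls carry little weight. The counts were 4 and 2 without HD replicate 1, 0 and 0 without HD replicate 2, 1165 and 600 without MF replicate 1, 70 and 30 without MF replicate 2, and 64 and 31 without MF replicate 3; with all samples 1605 genes had an unadjusted p under 0.05. The MF against HD change differed between HSC/MPP-like and erythroid-like cells for 2 genes that were higher and 1 that was lower of 14748 tested, with 1433 at an unadjusted p under 0.05. CXCL3 was among the higher ones, at 2.41 ± 0.21 (edgeR, Benjamini-Hochberg adjusted p = 0.0130), while VWF and C6orf25 differed by 2.65 ± 0.48 and 1.32 ± 0.25 and did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.167 for both). These counts were 0 and 0 without HD replicate 1, HD replicate 2 or MF replicate 1, 433 and 549 without MF replicate 2, and 9 and 9 without MF replicate 3.

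PF4, PPBP, VWF and C6orf25 were called higher in MF than in HD within HSC/MPP-like cells. For PF4 and PPBP, free RNA from megakaryocyte-like cells is a candidate source: their level in HSC/MPP-like cells was at most 1.26 times that in neutrophil-like cells of the same MF library. For VWF the tables argue against that source as the whole cause, since its level was 4.81 to 7.08 times that in neutrophil-like cells. HSC/MPP-like cells held at least 13.2 times as many VWF or C6orf25 UMIs per PF4 UMI as megakaryocyte-like cells. That ratio cannot decide, because HD HSC/MPP-like cells already held C6orf25 (6.35 CPM) and VWF (2.07 CPM) with almost no PF4 (0.0846 CPM). For C6orf25 free RNA stays open, at 1.89 to 2.40 times its level in neutrophil-like cells. From HD to MF it also went from 19.3 to 54.5 CPM in erythroid-like and from 6.03 to 49.1 CPM in eosinophil/basophil/mast-like cells. For VWF and C6orf25, doublets with a megakaryocyte-like cell are argued against, since at least 79.6% of the UMIs of each gene came from HSC/MPP-like cells without PF4 or PPBP. A difference between MF and HD stem-like cells and an effect of mobilization stay open. The HSC/MPP-like class also came from different clusters in MF and HD, so a difference in its cell mixture stays open too.

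Of 29 heat shock and immediate early genes 5 were called lower in MF in whole libraries. A subset of HD cells as the whole cause is argued against: without the clusters led by heat shock genes, the median log2 change of the 5 called list members was −3.30, against −4.34 with them, and 3 were still called. HSPA1A was called lower in 3 of 3 classes compared. Handling or mobilization of the HD samples could give such a fall, and it cannot be told apart from the disease because the design has no HD sample without mobilization.

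Megakaryocyte-like cells took a larger share of MF than of HD cells. Doublets of other classes are argued against: 20 of the 28 megakaryocyte transcription and signalling genes, none used in the clustering, lay above every other named class in every MF library. The lowest MF share was at least 3.82 times the highest HD share in each of 5 clusterings and by marker score. Only 1 of these clusterings, with genes centred within each library, took library differences out. There the lowest MF share was 2.56% and the highest HD share 0.191%, which argues against clusters that follow libraries and so hide such cells in HD. By marker score the ratio was lowest, and 37.2% of the class in MF replicate 1 lay near the boundary. The disease and mobilization stay open as explanations. For the comparison of megakaryocyte-like with other cells within MF, which called 188 list genes, 10 splits of the 6 sums are too few for a share under 0.05. The highest of the other splits gave 0, and 1 of 10 gave as many as the real one, itself. Each other split put megakaryocyte-like and other sums on the same side, which favours a count near 0, so the splits cannot decide.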

How the results depend on the processing

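The settings without clusters led by heat shock genes and without marker genes in the clustering, and the comparison of HSC/MPP-like with erythroid-like cells, were chosen after the results had been seen; the other settings were planned. Of 8046 pairs of a named gene and a setting, 7235 kept their direction and side of the threshold, 354 were no longer called, 450 became called and 7 reversed. The pairs kept include genes that were not called in either setting, so their number does not measure how stable the calls were. Only 42 of the 104 genes in whole libraries and 31 of the 105 in HSC/MPP-like cells were called in the main setting. Of 90 differences in class shares 86 kept their direction, as did 121 of 126 differences in shares of cells with a UMI. Every cell passed the cell filter, so leaving it out changed nothing, and no other clustering gave 2 HD libraries with 20 megakaryocyte-like cells, so that comparison had no value there. Leaving out an HD sample left 1 HD library, assumed to vary like the others. Causes were not tested except where given.

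The DESeq2 test called 527 higher and 400 lower genes in whole libraries, 194 and 201 in HSC/MPP-like, 73 and 94 in erythroid-like, 98 and 114 in megakaryocyte-like cells by marker score, and 5 higher in eosinophil/basophil/mast-like cells. It called 27 lower genes for the megakaryocyte contrast between groups, and 58 and 49 for HSC/MPP-like less erythroid-like cells. Without a filter on low counts the numbers were 292 and 247 in whole libraries, 294 and 359, 168 and 173, and 28 and 47 in HSC/MPP-like, erythroid-like and eosinophil/basophil/mast-like cells, 288 and 158 by marker score, and 163 and 113, and 209 and 271, for the contrasts. DESeq2 size factors gave 1 higher gene in eosinophil/basophil/mast-like cells. Thinned cells gave 20 higher genes by marker score.

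Replicate numbers only name libraries and were not taken to pair the samples. Across genes, the deviations of same-numbered samples correlated at −0.134 and −0.0747. With only 2 HD libraries the HD deviations mirror each other, so these values cannot decide on pairing. With the replicate block the counts were 296 and 228 in whole libraries, 157 and 176 in HSC/MPP-like cells and 68 and 64 by marker score. Without the sample block, 54 higher and 38 lower genes were called for megakaryocyte-like against other cells within MF.

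At resolution 0.5, 3 higher and 0 lower genes were called by edgeR in HSC/MPP-like cells, which then numbered only 20 and 47 in 2 MF libraries. There the log2 changes of CD84 (−1.45), HSPA6 (0.61), HSPA1A (0.015), BAG3 (0.25), VWF (−8.63), BCL6 (0.19) and SLC2A3 (0.39) reversed, on these few cells. Erythroid-like cells had 14 higher genes at resolution 0.5, 12 lower at resolution 2, 29 and 71 with genes centred within libraries, and 5 higher by marker score. Eosinophil/basophil/mast-like cells had 18 and 21 at resolution 2, 2 higher with centring, 14 and 38 by marker score, and 1 higher without marker genes in the clustering. By marker score 65 genes were higher in HSC/MPP-like cells and 63 lower in megakaryocyte-like against other cells within MF. Without clusters led by heat shock genes 128 genes were higher in whole libraries, and 0 higher and 4 lower in erythroid-like cells, most of whose HD cells were in such a cluster. The lists called in whole libraries (8 higher, 7 lower) and HSC/MPP-like cells (6 and 5) came to 0 and 0 with an estimated correlation and with fry.

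The erythroid-like share difference was −1.01 points with centring. The lymphoid progenitor-like difference was −2.91 at resolution 0.5, −4.75 by marker score and −3.06 without MF replicate 1 (−3.06 to 7.78 over the samples left out).

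Leaving out each sample gave 6 to 393 higher and 21 to 255 lower genes in whole libraries (lowest without HD replicate 1, highest without MF replicate 1; 7 and 36 without HD replicate 2, 133 lower without MF replicate 2). It gave 10 to 80 and 20 to 119 in HSC/MPP-like cells (lowest without HD replicate 2; 80 higher without MF replicate 1, 75 and 119 without MF replicate 2, 21 higher without HD replicate 1), and 0 to 81 and 6 to 177 in erythroid-like cells (lowest without HD replicate 2, highest without MF replicate 2; 1 and 9 without HD replicate 1, 18 higher without MF replicate 3). In eosinophil/basophil/mast-like cells the ranges were 0 to 2 (highest without MF replicate 1) and 6 to 16 (without HD replicate 2 and HD replicate 1). For megakaryocyte-like against other cells within MF they were 85 to 94 and 75 to 94. By marker score they were 2 to 523 and 8 to 334 (lowest without HD replicate 1, highest without MF replicate 1; 2 and 11 without HD replicate 2, 9 and 24 without MF replicate 2). For the megakaryocyte contrast between groups they were 0 to 1165 and 0 to 600 (without HD replicate 2 and MF replicate 1; 4 and 2 without HD replicate 1, 70 and 30 without MF replicate 2, 64 and 31 without MF replicate 3), and for HSC/MPP-like less erythroid-like cells 0 to 433 and 0 to 549 (0 without HD replicate 1, HD replicate 2 or MF replicate 1, highest without MF replicate 2; 9 and 9 without MF replicate 3). Lists numbered 7 to 9 higher and 4 to 7 lower in whole libraries (4 without MF replicate 1) and 4 to 7 and 4 to 8 in HSC/MPP-like cells (8 without MF replicate 2).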

Other observations

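The edgeR tests below were planned; the genes were picked out, and the comparison with neutrophil-like cells was chosen, after the values had been seen.

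HIST1H2AC, a histone H2A gene, stood at 29.4 ± 10.7 CPM (SD, n = 3) in MF and 371 ± 112 (SD, n = 2) in HD in whole libraries, and fell by 3.66 ± 0.36 on the log2 scale (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00701). The log2 change was −3.17 ± 0.38 in HSC/MPP-like, −3.50 ± 0.31 in erythroid-like and −2.74 ± 0.32 in eosinophil/basophil/mast-like cells (edgeR, Benjamini-Hochberg adjusted p = 0.00739, 0.00359 and 0.00119). HIST1H2BG fell by 3.68 ± 0.34 in whole libraries. Histone genes have near-identical copies, so counts of single genes are uncertain.

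RPS26, a ribosomal protein gene with near-identical pseudogenes, stood at 494 ± 75.4 CPM (SD, n = 3) in MF and 1732 ± 235 (SD, n = 2) in HD and was the only 1 of 80 ribosomal protein genes called in whole libraries (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0172). RGS1, which limits signalling of chemokine receptors, had a log2 change of −3.30 ± 0.29 in whole libraries and −2.65 ± 0.29 in HSC/MPP-like cells (edgeR, Benjamini-Hochberg adjusted p = 0.00444 and 0.00568). Of genes called higher in MF HSC/MPP-like cells, RXFP1, MEG3 and VWF stood at no less than 2.53, 8.63 and 4.81 times their level in neutrophil-like cells in each MF library, and C6orf25 and QPRT at no less than 1.89 and 1.82 times. PF4, PPBP, HBB and CD84 stood at no more than 1.26, 0.977, 1.37 and 0.796 times that level.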
